A study of Mus musculus with 8 samples.

How the data were processed

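Total RNA from 8 leukaemia samples, 4 per genotype, was sequenced by the authors, and each sample's processed table was used. The submitters' processing notes name STAR, HTSeq, DESeq and the mouse build mm9, without roles or versions. Each deposited table gives 18860 genes by Ensembl identifier and symbol with a single signal value, and the deposited values are not whole counts. Every deposited signal value is 1 plus a whole multiple of a step that is fixed within a library, as the values themselves show, so each is a read count divided by a size factor with 1 added. Dividing by the step gave whole reads for 100% of the values, within a tolerance of 0.02, and edgeR on those reads called 1 gene. The recovered totals were 30502718 to 35719495 reads per library, and 3 reads correspond to deposited values between 3.663 and 4.29. No molecular identifiers are named in the sources used here. The exact Poisson intervals, given for BC018473 and St6galnac1, cover counting error only. Intervals of log2 differences come instead from the limma fit and reflect the spread between libraries. Whether the counting used strand and how reads shared between gene copies were treated are not given in the sources used here.

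Groups were taken from the sample titles. The test planned for counts was edgeR's quasi-likelihood test; since the deposited values are not counts, the test named for that case was used, limma with a mean-variance trend on the log2 of the deposited value. The deposited 1 served as the pseudocount, so the fold of a gene with few reads is understated. Genes with a value of at least 10 in at least 4 libraries were tested (14679), with group as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. For the median level of the interval genes, each gene's log2 value relative to its mean in the p53-loss-only group was taken, the median over genes formed in each library without Trp53, and groups compared by an exact permutation test over 70 arrangements. Gene lists with at least 5 tested genes were compared with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry; genes of the interval were removed from every other list. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

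The interval list holds 101 genes from Sco1 to Alox12, written from knowledge of the gene order, of which 79 had a row and 65 besides Trp53 were tested. It is incomplete: 7 further tested genes that were not matched to it lie there. Among them is the row the authors name Rnasek, which is on the list but whose identifier carries another symbol in the annotation used for matching. Another is 2810408A11Rik, which the list names only as an alternative symbol of Tmem256. Lists were written before the data were examined, and symbols were matched by Ensembl identifier to a current annotation of another build, GENCODE for GRCm38, which gave a symbol to 17888 of the 18860 identifiers. That annotation was used for symbols and for which genes neighbour each other, and no coordinates are given.

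Genes named in the text follow a rule written before the data were examined. They are Trp53, Nf1 and Mll3, then Eif5a, Alox8 and Alox12, then the 6 interval genes with the smallest p. Outside the interval they are up to 10 genes per direction past the threshold with a mean of at least 1 CPM and no overlap, filled to 5 with the smallest p, leaving out predicted genes, and for each described list up to 4 members with the smallest p. Other genes named were chosen after their values were seen, and some genes that the rule takes are not reported here.

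The procedures were tested on simulated data made from these libraries' means and dispersions over 14679 genes. At the observed dispersion limma called 4.17% of genes lowered by 1 on the log2 scale, 4% of those raised by 1, 50% of those raised by 2 and 74% of those raised by 3, and 3 of 14304 unchanged genes. A simulated list of 60 genes lowered by 1 on the log2 scale gave a median difference of -1.03 (exact permutation p = 0.0286). The simulated genes varied independently, whereas the interval list had an estimated correlation between genes of 0.115. The simulation therefore does not show how the test of medians behaves with correlated genes.

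Alternatives were another normalization, 2 other filters, edgeR and DESeq2 on the recovered reads, limma voom with sample weights, each library left out, the replicate number as a block, values rescaled with TMM factors and an added constant of 5. The use of the planned edgeR test with TMM on the recovered reads, the rescaled values and the constant of 5 were chosen after seeing the data. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 93.4 in every pair), which argues against the same RNA sequenced again. Each was counted as 1 replicate, though this does not show that the libraries came from separate animals.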

Results

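Total RNA was sequenced from leukaemia cells taken from the bone marrow of moribund C57BL/6 mice of 2 genotypes. All the leukaemias carried Vav1-Cre, a recombinase active in blood cells, and short hairpin RNAs against Nf1, a brake on Ras signalling, and against Mll3 (current symbol Kmt2c), a histone methyltransferase. In the 11B3-deleted group (n = 4 libraries) 1 chromosome 11 lacks the 11B3 interval, which contains Trp53, and the other chromosome carries the floxed Trp53 allele. In the p53-loss-only group (n = 4 libraries) both Trp53 copies are the floxed allele and the rest of the interval is present on both chromosomes. The comparison asks which genes differ when a chromosomal segment is lost together with Trp53, rather than Trp53 alone. The labels speak of lines and do not say that each came from a separate animal, so p-values measure the spread between these libraries. The reads recovered per library numbered 30591456 to 35719495 in the 11B3-deleted group and 30502718 to 33365364 in the p53-loss-only group. Values below are the deposited values, which are read counts scaled for library size plus 1, given as mean ± SD.

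The engineered genes were examined first. Trp53 stood at 392.5, 387.3, 266.6 and 189.2 in 11B3-deleted replicates 1 to 4, and at 425.3, 577.1, 367.2 and 300.2 in p53-loss-only replicates 1 to 4. The difference did not pass the test (log2 difference -0.45, SE 0.32, 95% interval -1.18 to 0.27, limma adjusted p = 0.996). That range includes both 0 and -0.92, the median log2 difference of the other tested genes of the 11B3 interval. Reads of Trp53 therefore do not check the labels, and the floxed allele can still give RNA from exons outside the part removed. Nf1 was at 718.6, 516.5, 718.3 and 404.8 in the 11B3-deleted libraries and at 642.8, 820.3, 550.4 and 596.3 in the p53-loss-only libraries. Mll3 was at 3384.9, 3420.9, 3162.8 and 2957.4 against 2655.8, 4268.8, 2818 and 3228.7. Neither hairpin target differed detectably between the groups, with 95% intervals of the log2 difference from -0.74 to 0.4 for Nf1 and from -0.38 to 0.41 for Mll3. Both groups carry both hairpins, so these values give no measure of the knockdown.

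Genes of the 11B3 interval fell together in the 11B3-deleted leukaemias, to 51.7% of the p53-loss-only level. This figure comes from the median over 65 tested interval genes other than Trp53, taken in each library relative to the p53-loss-only mean. The library median was -0.93 ± 0.23 on the log2 scale in the 11B3-deleted group (SD, n = 4) and 0.02 ± 0.07 in the p53-loss-only group (SD, n = 4). The difference was -0.95 (two-sided exact permutation test, p = 0.0286, the smallest p that 70 arrangements allow). Each 11B3-deleted library lay below each p53-loss-only library, at -0.95, -1.17, -0.62 and -0.98 for replicates 1 to 4. Of the 65 genes, 63 had a lower mean and 2 a higher one, Myh10 (log2 difference 1.84, SE 1.54) and Bcl6b (0.13, SE 0.65), both within their error. In 35 genes, or 53.8%, the groups did not overlap, all of them lower in the 11B3-deleted group, where chance gives 2.86%.

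**Figure D1:**
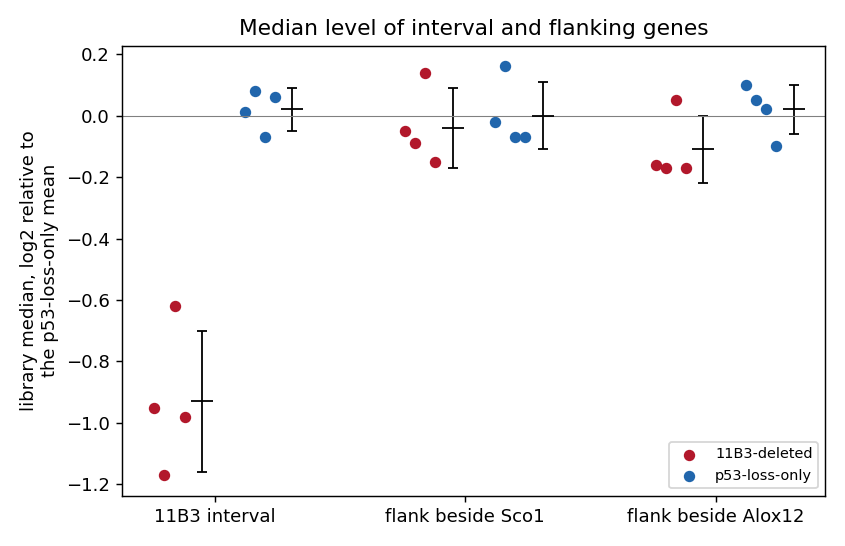
Median log2 level of the genes of the 11B3 interval and of its 2 flanks in each library, relative to the mean of the p53-loss-only group. Points are libraries, bars are group means with SD (n = 4 each), and the interval medians of the 11B3-deleted libraries lie between -1.17 and -0.62 while the flank medians lie between -0.17 and 0.16 in all 8 libraries.

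Taken gene by gene, 46 interval genes were lower with Benjamini-Hochberg adjustment of the limma test, adjusted over the list alone, and none was higher. Over all genes tested, 0 interval genes passed with limma (smallest adjusted p = 0.133), although 47 were lower at an unadjusted p under 0.05. For the listed genes the count over all genes was also 0 with edgeR and was 21 with DESeq2. Of the 73 tested genes that lie from Sco1 to Alox12 in gene order, 7 were not matched to the list, all 7 with a lower mean (median log2 difference -1.32). DESeq2 called 2 of these 7, 9330160F10Rik and Rnasek, which makes 23 by place. The 6 genes with the smallest p all fell, adjusted over the list alone. Gabarap, a ubiquitin-like protein of autophagosomes, was at 3484 ± 282.3 against 7807 ± 1113 (SD, n = 4 each), a log2 difference of -1.16 (SE 0.15, limma adjusted p = 0.00171 over the list alone). Rpl26, a protein of the large ribosomal subunit, was at 49.4% of the p53-loss-only level, Ndel1, a dynein regulator, at 47.5%, and Trappc1, a vesicle tethering factor, at 44.8%. Phf23 was at 49.7%. The lysosomal glycoprotein Cd68, abundant in macrophages, was lowest of the 6, at 22.4% (log2 difference -2.16, SE 0.34, limma adjusted p = 0.00178 over the list alone).

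Eif5a, a translation factor that carries the amino acid hypusine, was at 17830 ± 5262 in the 11B3-deleted group and 29210 ± 6056 in the p53-loss-only group (SD, n = 4 each). It fell to 59.9% of the p53-loss-only level (log2 difference -0.74, SE 0.25, limma adjusted p = 0.0253 over the list alone and 0.996 over all genes), and the 4 libraries of each group did not overlap. Alox12, a lipoxygenase gene at the end of the interval, was at 17.21 ± 6.85 against 18.88 ± 6.15 (SD, n = 4 each), a log2 difference of -0.15 (SE 0.44, 95% interval -1.13 to 0.84) that did not pass the test. Alox8, another lipoxygenase, lay between 1 and 2.1 in every library, below the value of 3 reads in each, so no fold is given. Of the abundant interval genes, Eif4a1, an RNA helicase of translation initiation, differed by -0.92 (SE 0.23), and Polr2a, the large subunit of RNA polymerase II, by -0.92 (SE 0.17), both past the threshold over the list alone; these genes were chosen after their values were seen.

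**Figure D2:**
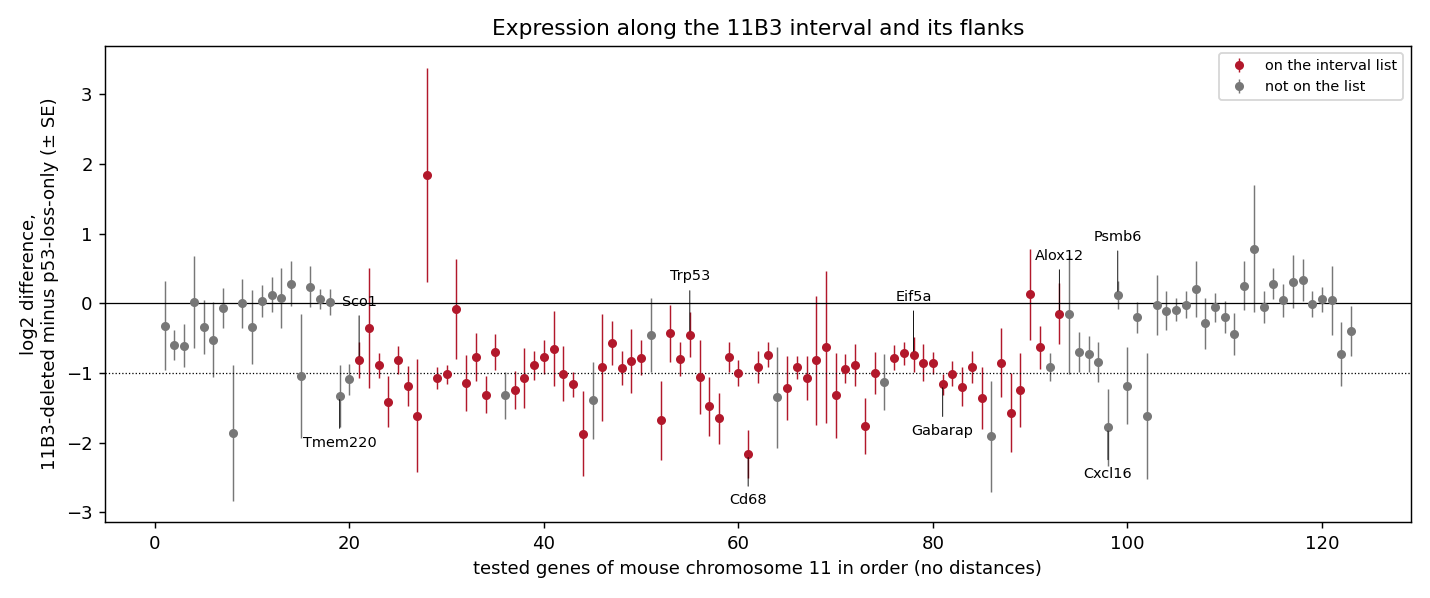
Log2 difference (11B3-deleted minus p53-loss-only, with SE) of each tested gene of chromosome 11 around the interval, in gene order without distances. Red points are genes matched to the interval list, grey points are other genes, and the dotted line marks -1. The quartiles of the matched interval genes other than Trp53 are -1.19 and -0.77.

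The genes flanking the interval were measured in the same way as background. Beside Sco1, 17 tested genes had library medians of -0.04 ± 0.13 against 0 ± 0.11 (SD, n = 4 each; exact permutation test, p = 0.514). Beside Alox12, 29 tested genes had library medians of -0.11 ± 0.11 against 0.02 ± 0.08 (SD, n = 4 each, exact permutation test, p = 0.114). The centring on the p53-loss-only mean was not repeated for each arrangement. With each gene set against its mean over all 8 libraries, the exact permutation test gave p = 0.629 beside Sco1 and p = 0.0571 beside Alox12. On the Sco1 side 2310004I24Rik (current symbol Adprm), the gene next to Sco1, fell to a log2 difference of -1.09 (SE 0.22), the only flank gene past the threshold over its list alone with limma; DESeq2 called it over all genes (log2 difference -1.06, DESeq2 adjusted p = 0.00197). Tmem220, the next gene, had -1.33 (SE 0.44), and neither gene's groups overlapped. On the Alox12 side none passed, and Pelp1 (-0.7, SE 0.29), Arrb2 (-0.73, SE 0.26), Med11 (-0.84, SE 0.29) and Cxcl16 (-1.78, SE 0.55) had unadjusted p values under 0.05. Psmb6, which follows Cxcl16 among the tested genes, had 0.12 (SE 0.2).

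Outside the interval, 2 of 14679 tested genes passed the limma test after Benjamini-Hochberg adjustment over all genes, both lower in the 11B3-deleted leukaemias. BC018473, annotated as an antisense RNA gene, gave 3 reads in the 4 11B3-deleted libraries together and 35675 in the p53-loss-only libraries, or 0.00812% after scaling (exact Poisson interval 0.00167% to 0.0237%, 95%, counting error only; limma adjusted p = 0.00553). St6galnac1, a sialyltransferase that builds the sialyl-Tn antigen, gave 1 read against 1352, or 0.0714% (exact Poisson interval 0.00181% to 0.399%; limma adjusted p = 0.0372). In the p53-loss-only replicates 1 to 4 BC018473 was at 736.1, 10093.5, 10173.4 and 15591.1 and St6galnac1 at 39.8, 388.1, 390.3 and 570.7. Both lie on chromosome 11 next to each other among the tested genes, away from the 11B3 interval. Whether counting used strand is not given in the sources used here, so reads of BC018473 could come from a gene on the other strand. With edgeR on the recovered reads 1 gene, BC018473, passed, with DESeq2 71 genes passed (57 lower, 14 higher), of which 21 are on the interval list and 50 are not, and limma voom with sample weights called 0. Leaving out 11B3-deleted replicate 2 also left 0, and leaving out another 11B3-deleted replicate left 1, BC018473. Leaving out any p53-loss-only replicate left 0, because both genes then no longer met the filter.

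**Figure D3:**
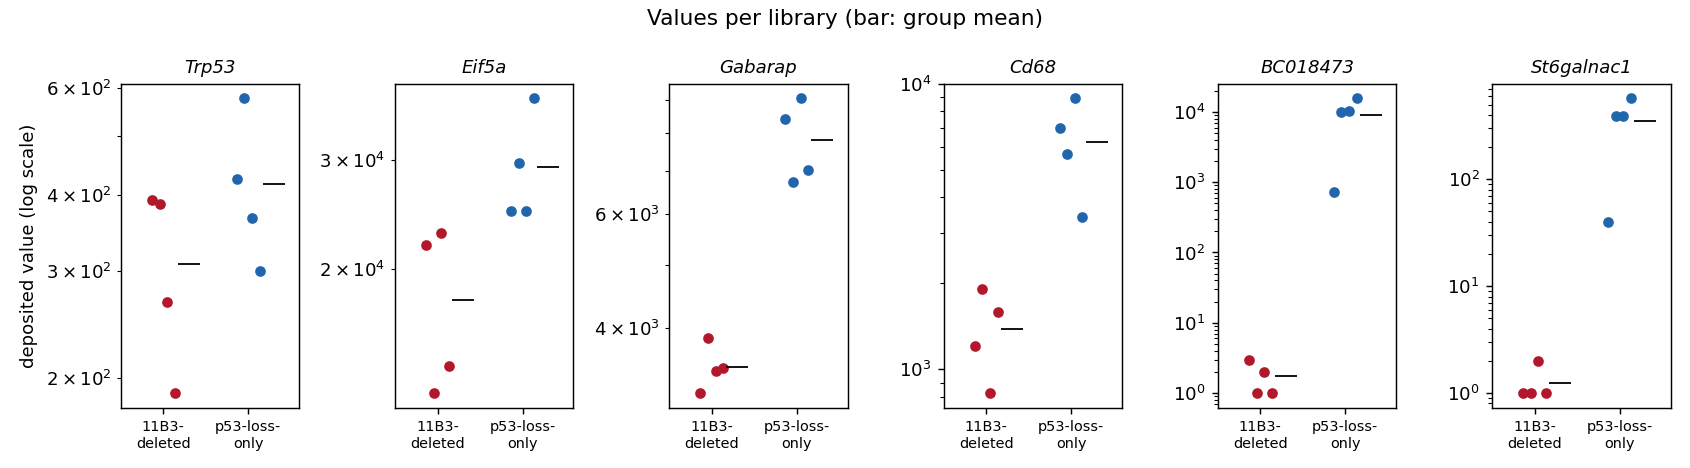
Deposited values of 6 genes in each library, on log axes that differ between panels, with 11B3-deleted libraries in red, p53-loss-only libraries in blue and bars at the group means. BC018473 lies between 1 and 3 in the 11B3-deleted libraries and between 736.1 and 15591.1 in the others, whereas the Trp53 values overlap.

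No gene was higher past the threshold with limma and 14 were with DESeq2. With limma, 173 genes were higher and 350 lower at an unadjusted p under 0.05, 523 in all against 734 that chance gives. The groups did not overlap in 315 genes, or 2.15%, where chance gives 2.86%. The genes outside the interval with the next smallest p did not pass with limma and are given as values. Trpv4, a cation channel, was at 57.9 ± 11.66 against 189.8 ± 37.36, Trim46 at 48.48 ± 13.92 against 211.4 ± 53.88, and Nav1 at 536.7 ± 89.69 against 1235 ± 263.2 (SD, n = 4 each). On the other side, Xlr3b, an X-linked gene, was at 131.8 ± 110.7 against 3.138 ± 3.027, and Ptger3, a prostaglandin E2 receptor, at 332.3 ± 344.7 against 14.62 ± 11.19 (SD, n = 4 each). Mier3 was at 1893 ± 232.9 against 1077 ± 269.5, the chromatin protein Hmgb2 at 16470 ± 1756 against 11110 ± 1056, and Serpina3n at 83.16 ± 69.4 against 13.94 ± 8.586 (SD, n = 4 each). With DESeq2 all of these except Mier3 passed.

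Of 30 gene lists fixed beforehand, 12 passed camera with a preset correlation of 0.01, and 1 of them, the 11B3 interval, also passed with an estimated correlation (adjusted p = 0.0114) and with fry (adjusted p = 0.00341). That adjusted p became 0.0741 without 11B3-deleted replicate 4 and 0.0589 without p53-loss-only replicate 2. For each of the other 11 lists the adjusted p was 0.555 with an estimated correlation. Library medians of each list, with each gene set against its mean over the 8 libraries, were also compared by an exact permutation test that was not among the tests fixed beforehand. The exact test gave p = 0.0286, the smallest possible, for the interval and the MLL3-MLL4 complex and 0.0571 or more for the other 28 lists, and none passed after Benjamini-Hochberg adjustment over the 30 lists (smallest adjusted p = 0.429). Leaving out any 1 of the 8 libraries kept the preset calls of the interval, immediate-early and stress, mitochondrial-encoded, cell cycle and erythroid lists, and ended those of the other 7 in at least 1 case, given with each list.

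The immediate-early and stress list was lower with the preset correlation (18 of 21 tested members lower, camera adjusted p = 6.42e-07; adjusted p = 0.555 with an estimated correlation). Fos, a component of the AP-1 transcription factor, fell, adjusted over the list alone, from 9650 ± 6617 to 1504 ± 136.6 (SD, n = 4 each), with no overlap between the groups. Jun was at 2295 ± 1006 against 11110 ± 8578, also without overlap, Fosb at 50.7 ± 36.54 against 749.7 ± 932, and the phosphatase gene Dusp1 at 1064 ± 264.6 against 2917 ± 1650 (SD, n = 4 each). Over all genes, no member of this list passed with limma. DESeq2 called Fos, Fosb and Jun (DESeq2 adjusted p = 1.76e-05, 0.00454 and 0.0454) but not Dusp1. Library medians of the immediate-early and stress list overlapped, at -0.34, -0.05, -0.3 and -0.87 against 1.05, 0.55, -0.15 and -0.01 (exact permutation test, p = 0.0571). Of the monocyte and macrophage list, 22 of 30 members were lower (camera adjusted p = 0.00139; adjusted p = 0.555 with an estimated correlation). Without p53-loss-only replicate 1 its adjusted p was 0.0608. Its member Cx3cr1, a chemokine receptor, was at 833.3 ± 512.5 against 2946 ± 779.5 (SD, n = 4 each). Mrc1, also among its 4 members with the smallest p, was higher, at 155.6 ± 26.89 against 93.73 ± 34.65 (SD, n = 4 each). The monocyte and macrophage library medians overlapped, at -0.39, 0.15, -0.48 and 0.05 against 0.66, 0.18, 0.56 and -0.71 (exact permutation test, p = 0.343). All 14 tested mitochondrial-encoded genes were lower (camera adjusted p = 1.07e-05; adjusted p = 0.555 with an estimated correlation), with mt-Co1, a subunit of cytochrome oxidase, at 254900 ± 3195 against 363900 ± 51440 (SD, n = 4 each). The library medians of the mitochondrial list overlapped, at -0.15, -0.39, 0.03 and -0.18 against -0.02, 0.29, -0.23 and 0.82 (exact permutation test, p = 0.2), highest in p53-loss-only replicate 4, where mt-Rnr1 was at 45801.2.

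Lists higher with the preset correlation were led by the cell cycle, with 38 of 41 members higher and a median log2 difference of 0.3 (camera adjusted p = 5.46e-07; adjusted p = 0.555 with an estimated correlation). The library medians of the cell cycle list overlapped, at 0.5, -0.44, 0.46 and 0.05 in 11B3-deleted replicates 1 to 4 against -0.26, -0.15, -0.41 and 0.33 (exact permutation test, p = 0.371). Cyclin B1 (Ccnb1) was at 3237 ± 773.7 against 2070 ± 233.3 (SD, n = 4 each). Of the erythroid list 31 of 33 members were higher (camera adjusted p = 4.14e-06; adjusted p = 0.555 with an estimated correlation), with carbonic anhydrase 1 (Car1) at 118943.5, 1554.9, 23898.4 and 5391 in 11B3-deleted replicates 1 to 4 and at 6160.2, 9175.1, 87.6 and 161.8 in p53-loss-only replicates 1 to 4. The library medians of the erythroid list overlapped, at 1.39, -0.59, 0.82 and 0.58 against 0.43, 1.73, -2.77 and -1.64 (exact permutation test, p = 0.343). Of the B cell list 20 of 21 members were higher (camera adjusted p = 1.07e-05; adjusted p = 0.555 with an estimated correlation). Its library median was 4.47 in 11B3-deleted replicate 3 and between -1.68 and 0.45 in the other libraries, and without that replicate the adjusted p was 0.244. The stem and progenitor list was not called without 11B3-deleted replicate 4 (adjusted p = 0.387), p53-loss-only replicate 3 (0.0713) or p53-loss-only replicate 4 (0.0804). Of this list 19 of 28 members were higher (camera adjusted p = 0.0235; adjusted p = 0.555 with an estimated correlation), with Bcl11a at 3555 ± 2434 against 749.8 ± 498.8 and Meis1 at 95.4 ± 113.9 against 16.34 ± 14.5 (SD, n = 4 each). The dendritic list (11 of 16 higher, camera adjusted p = 0.0236), marrow stroma and endothelium (19 of 22, 0.00463), oxidative phosphorylation (33 of 39, 0.00323) and translation initiation (26 of 29, 0.00957) were also higher, each with an adjusted p = 0.555 with an estimated correlation. The dendritic call ended without 11B3-deleted replicate 1 (adjusted p = 0.0826) or 4 (0.186) or p53-loss-only replicate 4 (0.488), and that of oxidative phosphorylation without 11B3-deleted replicate 1 (0.249) or 3 (0.0605). The call of translation initiation ended without 11B3-deleted replicate 1 (adjusted p = 0.5) or p53-loss-only replicate 1 (0.0608). That of marrow stroma and endothelium ended without 11B3-deleted replicate 2 (adjusted p = 0.279) or 4 (0.0556) or p53-loss-only replicate 3 (0.139) or 4 (0.0804).

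**Figure D4:**
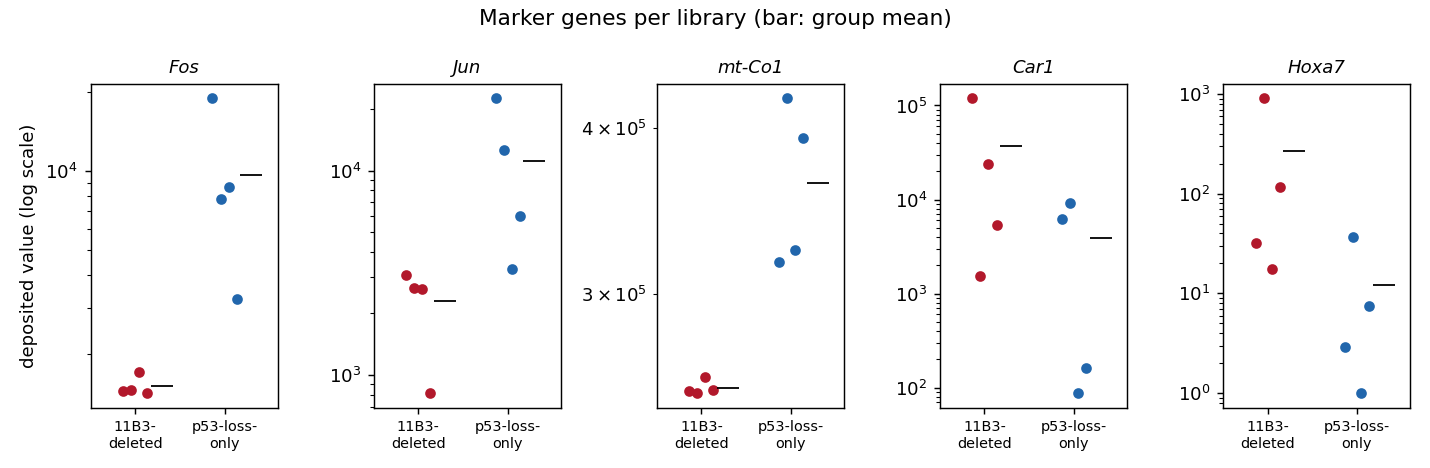
Deposited values of 5 marker genes in each library, on log axes that differ between panels, with 11B3-deleted libraries in red, p53-loss-only libraries in blue and bars at the group means. Fos and mt-Co1 do not overlap between the groups, while 1 library of the 11B3-deleted group lies far above the others for Hoxa7 (907.1).

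The remaining lists were not called with either correlation. Targets of p53 were split between 16 lower and 15 higher members (camera adjusted p = 0.937), with Pmaip1, an apoptosis gene, at 849.2 ± 511.9 against 1627 ± 497.5 (SD, n = 4 each). The lipoxygenase and prostaglandin enzymes had 12 lower and 14 higher members (camera adjusted p = 0.937), and the hypusine and polyamine pathway, without its interval genes, 7 lower and 10 higher (0.842). For Ras-MAPK output 12 of 19 members were lower (camera adjusted p = 0.127). Lists of primary granule genes (camera adjusted p = 0.579), neutrophil (0.441), megakaryocyte (0.961), mast cell, basophil and eosinophil (0.439), T and NK cell (0.115) and MHC class II genes (0.172) did not pass. Interferon response (camera adjusted p = 0.648), Bcl2 family and apoptosis (0.343), MLL3-MLL4 complex (0.172), cytosolic ribosomal proteins (0.301), glycolysis (0.0668) and sex-linked genes (0.519) did not pass either. The library medians of the MLL3-MLL4 complex list did not overlap, at 0.15, -0.01, 0.12 and -0.01 in the 11B3-deleted group against -0.15, -0.06, -0.22 and -0.03 (exact permutation test, p = 0.0286, adjusted p = 0.429). The flanks gave camera adjusted p = 0.624 beside Sco1 and 0.0519 beside Alox12. The test's direction was lower and the median log2 difference above 0 for the Sco1 flank (median 0.03, mean -0.15), lipoxygenase and prostaglandin enzymes (0.04, -0.02), the hypusine and polyamine pathway (0.04, -0.09) and megakaryocyte genes (0.17, with a mean of 0.09). With the preset correlation, some of these lists were called when 1 library was left out. Without 11B3-deleted replicate 2 these were cytosolic ribosomal proteins (adjusted p = 4.23e-05) and glycolysis (0.00282), and without 11B3-deleted replicate 3 the Alox12 flank (0.0104), Ras-MAPK output (0.019) and MHC class II (0.0412). Without 11B3-deleted replicate 4 they were primary granule (adjusted p = 0.00997), T and NK cell (0.00269) and interferon response (2.15e-05). Without p53-loss-only replicate 1 Ras-MAPK output was called (adjusted p = 0.0255), and without replicate 2 of that group MHC class II (0.0257). Without p53-loss-only replicate 3 the neutrophil (adjusted p = 0.0145), T and NK cell (0.0265) and glycolysis (0.0453) lists were called, and without p53-loss-only replicate 4 the Alox12 flank (0.00793) and interferon response (0.00197).

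Libraries of the same group were no more alike than libraries of different groups, with a median Pearson correlation of log2 values across genes of 0.938 over 12 same-group pairs and 0.945 over 16 pairs of different groups. The first principal component held 36.7% of the variance and did not separate the groups (exact permutation test, p = 0.429).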

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

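The scans of the flanks and the test of the 11B3 chromosome alone were chosen after the result was seen. For the tests with the monocyte list and of the heat-shock genes, the requirement that the quartiles, and not the median alone, lie past the stated bound was also set after the values were seen. In groups of 4 libraries, a library was singled out where its gap to the nearest other filled most of the group's range. This held in 9 of 136 groups examined. The rule's chance rate of about 1 in 20 assumes independent, normally distributed values. Most values here were unlogged and many of the genes share a list, so the count cannot be judged against that rate. In 11B3-deleted replicate 3, Ebf1 was at 3606.7 against 22.5 to 94.2 in the rest of its group, and Fcrla at 1281.4 against 36.5 to 64. The same library had Fos at 1707.9 (1415.7 to 1450.5 in the rest), St6galnac1 at 2 (1 in the rest, a difference of 1 read) and a median of 0.05 for the flank beside Alox12 (-0.17 to -0.16 in the rest). In 11B3-deleted replicate 2, Hoxa7 was at 907.1 against 17.5 to 117.3 and Dusp1 at 1457 against 890.3 to 981.2. Gata1 was at 5043.6 in 11B3-deleted replicate 1 against 142 to 812.3. The mitochondrial ribosomal RNA mt-Rnr1 was at 45801.2 in p53-loss-only replicate 4 against 9717.3 to 10830.8.

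Some genes next to both listed ends of the interval were lower too. On the Alox12 side, a step fitted outward at the interval's level took in 9 flank genes, out to Chrne, and a share of 0.0037 of 10000 shuffled gene orders reached as far. A missing segment that passes Alox12 is a candidate explanation. Inside the step, Psmb6 (0.12, SE 0.2, 95% interval -0.33 to 0.57) and Mink1 (-0.2, SE 0.22, -0.69 to 0.3) lay near 0. Their intervals exclude -0.92, the median of the 11B3 interval genes. For Psmb6 and Mink1 these values argue against an unbroken missing segment that takes them in. Pld2 (-1.18, SE 0.55, -2.43 to 0.08) and Chrne (-1.62, SE 0.9, -3.65 to 0.41) were lower, but their intervals include 0. Where a segment shorter than the fitted step would end stays open. The share of 0.0037 is for the reach out to Chrne and leaves each gene's SE aside, so it does not test a shorter segment. With the monocyte list as a covariate, the median of the genes in the step was -0.64 (quartiles -0.9 to -0.3), so fewer monocyte-like cells cannot be told apart: the median alone passed the bound that would argue against them, and the quartiles did not. On the Sco1 side the fitted step held 2310004I24Rik and Tmem220. A share of 0.181 of shuffled orders reached as far, too many to decide with 17 genes. The shuffles weigh every gene alike whatever its SE, so the shares do not rank the sides. By gene, 2310004I24Rik passed over its list alone, whereas no gene on the Alox12 side did. The next tested genes, Zkscan6 and Map2k4, were at 0.02 (SE 0.19) and 0.06 (SE 0.14). The 15 genes outside the step had a median of 0.06.

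BC018473 and St6galnac1 were near 0 in all 4 11B3-deleted libraries. Gm11735, a pseudogene beside BC018473 named after its values were seen, gave 0 reads there and 352 in the p53-loss-only group, at least 122-fold lower (3 reads over the group). An allele carried on the 11B3-deleted chromosome alone would leave the other chromosome's transcripts, yet the highest 11B3-deleted library was at 2.5% or less of the lowest p53-loss-only library for both tested genes. An inherited difference in background between the cohorts stays open. Of the 20 nearest tested neighbours, 2 had an unadjusted p under 0.05, St6galnac2 (-2.32) and 2900041M22Rik (-1.27). That is fewer than the 3 set beforehand, and a single linked variant need not change any neighbour. Over all 14679 tested genes, 523 had such a p. St6galnac2 and Mxra7 are the tested genes directly beside BC018473 and St6galnac1, and Mxra7 had -0.87 (limma unadjusted p = 0.351). In p53-loss-only replicate 1, Gm11735 was at 6.6%, BC018473 at 6.2% and St6galnac1 at 8.7% of the mean of the other 3 p53-loss-only libraries.

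The lower Fos and Jun values may reflect handling before lysis or a different mix of cells. With the monocyte list as a covariate, the immediate-early and stress list kept a median of -0.5 (quartiles -1.43 to 0.08): the median alone passed the bound that would argue against fewer monocyte-like cells, and the quartiles were too wide to decide. Heat-shock members had a median of -0.69, which met the bound set beforehand for handling as a cause, with Hspa1a at -2.15 and Hspa1b at -1.66 but Dnajb1 at 0.28 and Hsph1 at 0.47. Since the members went both ways, handling cannot be told apart from the genotype. A biological difference between the genotypes stays open for all 3 patterns, untested.

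Other splits of the 8 libraries bear on the counts. Of 35 splits, 1, the real one, gave as many interval genes over the list alone (46, highest other 2). That is the smallest share that 35 splits allow, so no other split came near, but the splits alone cannot exclude chance. For genes past the threshold over all genes, 2 splits gave as many (2, highest other 532), so chance cannot be excluded. The split with 532 genes puts 11B3-deleted replicates 1 and 3 with p53-loss-only replicates 2 and 4, the 4 libraries with a negative first principal component, and points to a structure of the samples that crosses the groups. For gene lists, 7 splits gave as many (12, highest other 15), so chance cannot be excluded.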

How the results depend on the processing

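The edgeR test with TMM was the test planned for counts. Its use on the recovered reads, the rescaled values and the constant of 5 were chosen after seeing the data. The median level of the interval genes stayed between -1.06 and -0.87 when a library was left out and between -0.96 and -0.93 under the filters, scalings and constant, past the threshold each time. The count of genes changed was 2 with limma and 1 with DESeq2 size factors in edgeR, 1 with edgeR and TMM, 1 with the constant of 5, 71 with DESeq2 and 0 with limma voom and sample weights. Leaving out a library gave 0 to 1; without a p53-loss-only library both genes fail the filter, and without 11B3-deleted replicate 2 the adjusted p of BC018473 was 0.0645. The count of listed interval genes over all genes was 0, and 21 with DESeq2, and over the list alone 34 to 47 under all settings. Gene lists called numbered 9 to 14, and with an estimated correlation 1, or 0 to 1 when a library was left out. The replicate numbers did not pair the libraries (correlations of deviations -0.03, -0.217, -0.414 and -0.243), and no library correlated best with its own number. With the replicate number as a block, 0 genes passed and 34 interval genes did over the list alone, 0 lists passed with an estimated correlation and 13 with the preset one. The interval median was -0.95 (exact sign flip, p = 0.125, the smallest 16 arrangements allow). Of 342 values of 21 named genes, 307 kept direction and side of the threshold, 13 passed and 12 no longer passed. In 10 the sign turned, all near 0: Mll3 was 0 with DESeq2 size factors in edgeR and with DESeq2, -0.02 with edgeR and TMM, and -0.07 to 0.16 when a library was left out, and Alox12 was 0.03 with limma voom and -0.39 to 0.02 when a library was left out. The causes were not tested. TMM rescaling moved the median gene from 0.01 to 0. DESeq2, limma voom and edgeR with TMM gave no value for the interval median, and DESeq2 none for the estimated correlation. Depth limits Alox8, whose values were at most 2.1.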

Other observations

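The genes below were chosen after their values were seen, and no explanation was tested. B lineage genes stood far above the other libraries in 11B3-deleted replicate 3. Pax5, a transcription factor of B cells, was at 1529.5 there and between 4.2 and 37.9 in the other 7 libraries. Genes of early B cells followed, with Vpreb1 at 4727.2 (5.6 to 71.9 in the others), Igll1 at 9387.4 (2.1 to 205.1) and Rag1 at 3889.7 (1 to 160.8). The myeloid granule gene Mpo was at 157150 in the same library, within the range of 75329 to 414041.1 over the others. The erythroid transcription factor gene Klf1 was at 3754.9 in 11B3-deleted replicate 1 against 33.9 to 1056 in the other libraries. The globin genes Hbb-b1 (6528.4) and Hba-a1 (4710.1) were instead highest in p53-loss-only replicate 2.

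Sex-linked genes varied within both groups. Xist was at 78858.3, 69852.7, 66312.8 and 417.3 in 11B3-deleted replicates 1 to 4 and at 232.1, 71810.7, 82.1 and 41056 in p53-loss-only replicates 1 to 4. The Y-linked Ddx3y was at 2255.3 in 11B3-deleted replicate 4 and at 3342.3, 1.9, 269.6 and 25.5 in the p53-loss-only replicates, with 1 in each remaining library. The third p53-loss-only library therefore had little of either transcript, and the fourth had Xist together with a low level of Ddx3y.

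Median levels of whole chromosomes, with interval genes left out and each gene set against its mean over the 8 libraries, were uneven in p53-loss-only replicate 4. Chromosome 1 was at -0.37 on the log2 scale and chromosome 15 at 0.33 in that library, and 9 of 20 chromosomes lay beyond 0.25. In 11B3-deleted replicate 1, chromosome 10 was at -0.39. At most 2 chromosomes lay beyond 0.25 in any of the other 7 libraries.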
